A study of Mus musculus with 8 samples.

How the data were processed

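CTCF ChIP-seq was made from 2 replicates per condition, called biological replicates in the labels, with 1% formaldehyde for 10 minutes, DNA sheared to 200 to 500 bp and an anti-CTCF antibody at a dilution of 1 to 200. A portion of 1% of each sample was kept as input. Per the submitters' processing notes, FastQC, Trimmomatic, BWA, SAMtools and MACS2 were used and the builds named are mm10 and GRCm38.p6. Their versions and settings are not given in the sources used here. A growth protocol shared by all samples also mentions etoposide, a topoisomerase inhibitor. No label gives it as the treatment of any sample, and it was not used to group samples.

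The authors deposited 1 region list for control and 1 for NMDA, with 33820 and 36193 regions. Both are named as output of the irreproducible discovery rate (IDR) procedure, which keeps regions that rank alike in both replicates. The NMDA list has the 20 columns of that output and the control list 10, and the lowest score was 540 in both. The score column that the authors deposited rises with reproducibility and reaches a ceiling of 1000. The deposited −log10 p-value of each region was the signal used here. In the NMDA list it equalled the sum of 2 per-replicate columns in 36193 of 36193 regions, within a tolerance of 0.001. Which column belongs to which replicate is not stated, so they are called the first and the second replicate column. The control list has no such columns, so the sum could not be checked there. Signals are the authors' values for each region and were only ranked within a list, since they grow with sequencing depth, which is unknown. The input libraries were not analysed here.

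Regions on the assembled chromosomes were kept, which left out 5 control and 7 NMDA regions. Merging overlapping regions within a list changed nothing. A region was shared if it overlapped the other list by at least 1 bp (bedtools 2.31.1) and list-only otherwise. Chance overlap and chance spacing came from 100 shuffles within chromosomes. Shares have 95% Wilson intervals and differences of shares Newcombe intervals. For the signal-matched difference, shared regions were reweighted to the list-only regions over 10 signal bins with at least 20 regions of each class, with 1000 bootstrap draws. Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes. The design named transcription start sites, but the table used here has no strand, so both ends of each gene span replaced them. Exons, introns and untranslated regions were not used here. CTCF motif content, GC and CpG content and motif strand, which the design also named, need a genome sequence and were not analysed here.

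For each of 18 gene lists fixed before the data were examined, the members with a region at an end (within 1 kb) or in the body (the span widened by 1 kb) were counted, with shared regions placed by their summits in the NMDA list. They were compared with 10000 random lists, a one-sided permutation of list membership within gene-length deciles, with Benjamini-Hochberg adjustment over the lists for each class of region. Random lists treat genes as independent, which neighbouring genes are not. Clustered protocadherins share regions among members, so a test of their counts is given only for list-only regions at gene ends. Of the imprinted genes, 5 names were not among the protein-coding genes and were left out. Replication-dependent histone genes were matched through older names.

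Named genes followed a rule fixed at the same time as the lists. At gene ends it took at most 15 members of the immediate early, later activity-regulated and CTCF lists with a list-only region, the 10 genes with the strongest NMDA-only and the 10 with the strongest control-only regions at an end, and the 5 strongest shared regions. It also took the 8 genes with the most NMDA-only and the 3 with the most control-only regions in the body, and up to 4 members of other lists. Gene models without an established name were passed over. Genes named outside it are said to be.

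The steps were tested on simulated data. After part of the control list was removed and the rest shifted, 99.9% of removed and 100% of kept regions were recovered among 33815. The shifts were small against the median region width, so this tested only the counting of overlaps. For a true matched difference of −10 points over 36186 regions, the mean estimate was −10.04 and 95 of 100 intervals held the true value. For a true difference of 0 these were −0.02 and 94. Of 200 simulated lists of 30 genes without enrichment, 5.5% had an unadjusted permutation p under 0.05, and 68.5% did with the odds raised 3-fold. These lists were tested for NMDA-only regions in gene bodies, which 14.0% of genes have. The share called at gene ends, where 4.28% of genes have one, or after adjustment was not tested and may be lower. A test of the covered width of regions called 3 of 100 unchanged sets of 15 regions and 100 of 100 sets lowered by 20 points. Alternatives were a stricter score (a global IDR of 0.01), other overlap definitions, an NMDA list limited to the length of the control list, other gene-end windows and gene types, unmatched random lists, a single replicate column, 20 signal bins, shared regions placed by the control list or by either list, and ranking by score. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.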

Results

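CTCF binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse cortical neurons, with and without stimulation by NMDA. CTCF is a zinc finger protein that binds DNA and, together with the cohesin complex, anchors chromatin loops. NMDA is an agonist of a class of glutamate receptors. The neurons came from Swiss-Webster embryos at embryonic day 16 and were used on day 13 in vitro. Stimulated cultures received 50 µM NMDA for 10 minutes and then recovered in medium without the drug for 50 minutes. The series holds 8 samples in 4 groups of 2 replicates: control ChIP, control input, NMDA ChIP and NMDA input. The comparison asks where CTCF was detected in cultures with and without NMDA stimulation. It rests on 1 list of reproducible regions per condition, each built by the authors over the 2 replicates. Each condition therefore enters as 1 list, no difference between conditions could be set against the spread between replicates, and all intervals below cover counting error only. The read depth of the libraries is unknown, since the lists hold no counts.

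CTCF was detected at a similar number of places in both conditions. The control list held 33815 regions on the assembled chromosomes and the NMDA list held 36186. The median region was 1123 bp wide in the control list and 1182 bp in the NMDA list, and the lists covered 41.6 and 47.1 Mb. The strongest shared region at a gene end lay at Nipsnap2 (chromosome 5, 129724217 to 129726176, mm10). It was followed by Sh3glb1 (chromosome 3, 144719270 to 144721349), Ap5s1 (chromosome 2, 131209528 to 131210942), Zbtb45 (chromosome 7, 13008830 to 13010623) and Vps36 (chromosome 8, 22191669 to 22193749). Their signal, the authors' −log10 p summed over the 2 replicates, ran from 1544 to 2028 in the NMDA list, against a list median of 90.9. Across the 36186 NMDA regions, the signals of the 2 replicates correlated with Pearson's r = 0.886 and Spearman's rho = 0.861. These correlations are across regions, which are not independent replicates. The first replicate column had a median −log10 p of 32.1 and the second 56.1.

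Most regions were found in both conditions. Of the control regions, 90.8% (95% Wilson interval 90.5 to 91.1) overlapped an NMDA region by at least 1 bp, and 84.5% (84.1 to 84.8) of the NMDA regions overlapped a control region. Shuffling the other list within chromosomes gave a mean overlap of 3.75% and 3.54%. This left 3117 control-only and 5616 NMDA-only regions. With the NMDA list limited to its strongest 33815 regions, as many as in the control list, the shares became 88.9% of control and 88.3% of NMDA regions, with 3770 control-only and 3964 NMDA-only regions.

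Regions found in 1 list alone were weak within that list. The median −log10 p was 28.5 (quartiles 23.2 and 37.5) in NMDA-only regions and 116 (56.8 and 222) in shared regions of the NMDA list. In the control list it was 50.4 (41.7 and 67.0) in control-only and 186 (97.1 and 332) in shared regions. Of the NMDA-only regions 98.5% (98.2 to 98.8) lay below the median signal of their list, as did 99.2% (98.8 to 99.4) of the control-only regions. In the weakest decile 52.5% of control regions and 34.4% of NMDA regions were shared, against 100% of control regions and all but 1 of the 3619 NMDA regions in the strongest decile.

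**Figure D1:**
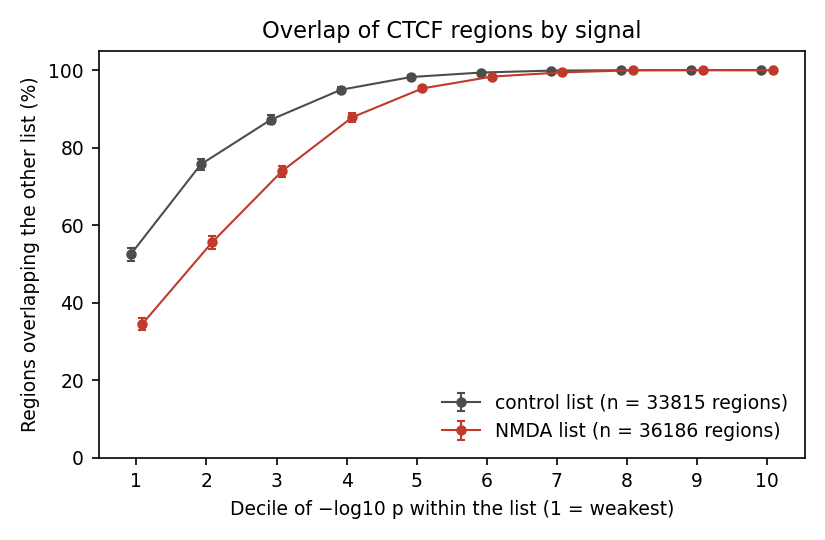
Percent of regions that overlap the other list (vertical axis) by decile of −log10 p within the list (horizontal axis), for the control list (grey) and the NMDA list (red), with 95% Wilson intervals. The share rises from 52.5% and 34.4% in the weakest decile to about 100% in the strongest.

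NMDA-only regions lay at the ends of protein-coding genes less often than either shared or control-only regions. A region counted as at a gene end when its summit lay within 1 kb of either end of an annotated gene span. The gene table used here gives no strand, so transcription start and 3′ ends were not separated. The share at gene ends was 14.8% (13.9 to 15.7) of NMDA-only regions, 17.6% (17.2 to 18.1) of shared regions of the NMDA list and 22.6% (21.2 to 24.1) of control-only regions. The difference between NMDA-only and shared regions was −2.83 percentage points (95% Newcombe interval −3.83 to −1.79), and that between NMDA-only and control-only regions −7.79 points (−9.54 to −6.07). Control-only regions were above shared control regions by 5.03 points (3.53 to 6.59). Compared with shared regions of the same signal deciles, the difference was −10.6 points (bootstrap interval −12.2 to −9.02) for NMDA-only and 2.48 points (0.645 to 4.30) for control-only regions. The matched NMDA-only difference was −3.81 points (−5.16 to −2.48) when the deciles used the first replicate column alone and −11.7 points with the second. It depended on the definition of a shared region. A reciprocal overlap of 50% gave −5.37 points (−6.73 to −4.07), and summits within 100 bp gave 0.663 points (−0.791 to 2.13). Without matching on signal these definitions gave 0.278 and 4.29 points. The matched control-only difference had an interval that included 0 when gene ends of all gene types were used or regions were extended by 500 bp. Intergenic regions made up 37.8% of NMDA-only and 31.0% of control-only regions.

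**Figure D2:**
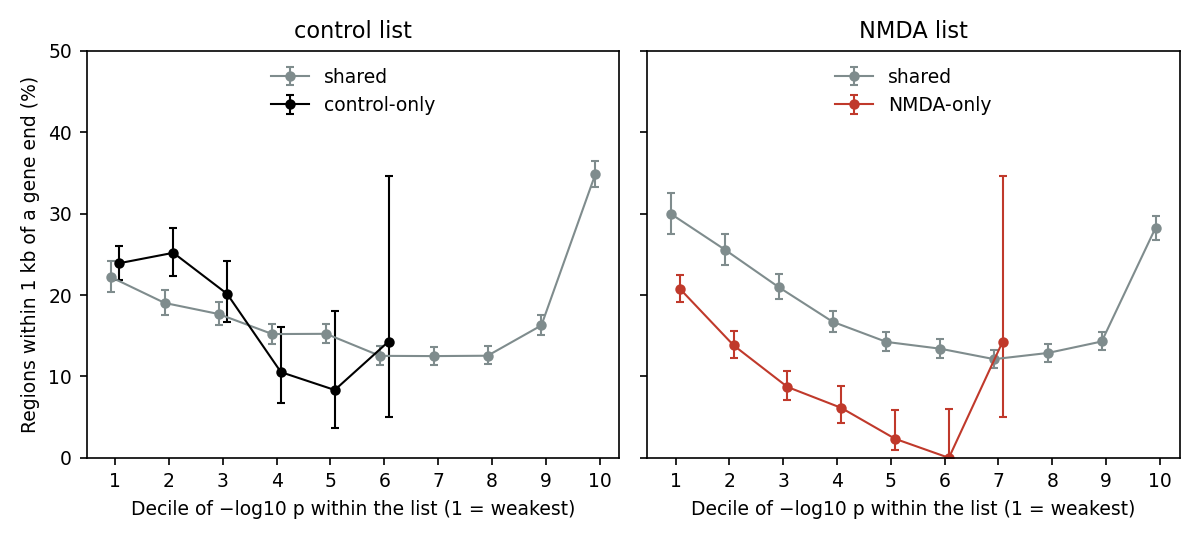
Percent of regions within 1 kb of a protein-coding gene end (vertical axis) by decile of −log10 p within the list (horizontal axis), for shared and list-only regions of the control list (left) and the NMDA list (right). Bars are 95% Wilson intervals and classes with under 20 regions in a decile are not drawn. In the weakest decile of the NMDA list the share is 20.8% of NMDA-only and 29.9% of shared regions.

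The strongest NMDA-only region at a gene end, with a −log10 p of 146, lay at Nuf2, a kinetochore gene (chromosome 1, 169531446 to 169532749), followed by Asb1 (chromosome 1, 91539677 to 91541290, 134). The third lay at Ddo, which encodes D-aspartate oxidase (chromosome 10, 40628743 to 40629770, 129). Cxxc1, a CpG-binding subunit of a histone methyltransferase complex, followed at 87.9 (chromosome 18, 74215664 to 74216772). Of the next 6, Guf1 (chromosome 5, 69556612 to 69557410), Polrmt (chromosome 10, 79746314 to 79748101) and Tufm (chromosome 7, 126486688 to 126487737) encode a translation factor, the RNA polymerase and an elongation factor of mitochondria. The others were Cplane2 (chromosome 4, 141213892 to 141215151), Zdhhc4 (chromosome 5, 143328975 to 143330038) and the proteasome subunit gene Psmd7 (chromosome 8, 107587812 to 107589241). These 6 had values from 61.7 to 74.4. At Nuf2 the replicates differed, with 23.1 in the first replicate column and 123 in the second.

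The strongest control-only regions at gene ends lay at the homeobox gene Gbx1 (chromosome 5, 24526193 to 24527514, −log10 p 189.8) and at Map1a, which encodes a microtubule-associated protein of neurons (chromosome 2, 121289198 to 121290620, 189.1). Rwdd1 (chromosome 10, 34018724 to 34020138) had 184 and Slc44a5 (chromosome 3, 153972745 to 153973970) had 155. The other 6, from 120.9 to 142, were the growth factor gene Fgf3 (chromosome 7, 144838485 to 144840269), the cholesterol exporter gene Abca1 (chromosome 4, 53030139 to 53031133), Arsg (chromosome 11, 109472064 to 109474749), Mbd3 of the NuRD chromatin remodelling complex (chromosome 10, 80398175 to 80399582), Dpp6, which encodes an auxiliary subunit of potassium channels (chromosome 5, 26817100 to 26818070), and the cell cycle gene E2f2 (chromosome 4, 136171990 to 136173332). Over all 21883 protein-coding genes, 936 had an NMDA-only region at an end, 772 had a control-only region and 5642 had a shared region.

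Immediate early genes, which are transcribed within minutes of neuronal activity, carried mostly shared regions. So did the NMDA list as a whole, where 84.5% of regions were shared. Gene lists were compared with 10000 random lists by a one-sided permutation test within deciles of gene length, adjusted over the 18 lists by the Benjamini-Hochberg method. Shared regions were placed by their summits in the NMDA list. Of the 31 members, 14 had a shared region at an end, against a mean of 7.60 in random lists (adjusted permutation p = 0.0459). Placed by the control list they lay at 15 members, and by either list at 17, where Ccn1, Gadd45g and Junb, named after their values were seen, were added. The call was lost under 5 of 9 alternative settings, over which the adjusted permutation p ran from 0.0024 to 0.608. Within the gene span widened by 1 kb, 22 of 31 had a shared region against 11.3 (adjusted permutation p = 0.0009), 4 an NMDA-only region against 2.38 (adjusted permutation p = 0.633) and 1 a control-only region against 1.58 (adjusted permutation p = 1). Examples at gene ends were Sik1 (chromosome 17, 31855861 to 31856935, −log10 p 525 in the NMDA list), Dusp1 (chromosome 17, 26508630 to 26510626, 257) and Egr4 (chromosome 6, 85509978 to 85514120, 159). Npas4, a transcription factor gene, was the only member with an NMDA-only region at an end (chromosome 19, 5003360 to 5004434, −log10 p 50.3), against 1.32 members in random lists (adjusted permutation p = 1). That region lay beside a shared region with a signal of 591 (5001472 to 5003325), and it was no longer NMDA-only when regions were extended by 500 bp. A further NMDA-only region lay inside the gene (4992925 to 4993286). Nr4a1, which encodes a nuclear receptor, had a control-only region at an end (chromosome 15, 101253699 to 101254763, 50.8) and an NMDA-only region inside (101259266 to 101260780, 22.8). Arc, named here after its values were seen, had no region within 1 kb of its span in either list. With shared regions defined by a reciprocal overlap of 50%, or by summits within 100 bp, 8 members had an NMDA-only region at an end (adjusted permutation p = 0.0045 and 0.0135, against 0.876 to 1 under the other 5 settings). In the summit definition these were Npas4 and 7 genes whose NMDA region overlapped a control region with its summit elsewhere: Atf3, Dusp1, Egr1, Egr4, Ier5, Klf10 and Nr4a3. At Atf3, Dusp1, Klf10 and Nr4a3 the control region overlapped several NMDA regions. Another of these had its summit 7 to 36 bp from the control summit, so the control summit kept a match there. The control region at Egr1 also overlapped 2 NMDA regions. The random lists were matched on gene length only, and the immediate early genes had more shared regions at ends (14 against 7.60 members). Their shared control regions there were also wider, with a median of 2313 bp against 1351 bp at all gene ends. The p-values for the 8 members thus mix having a wide region with having a changed one.

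**Figure D3:**
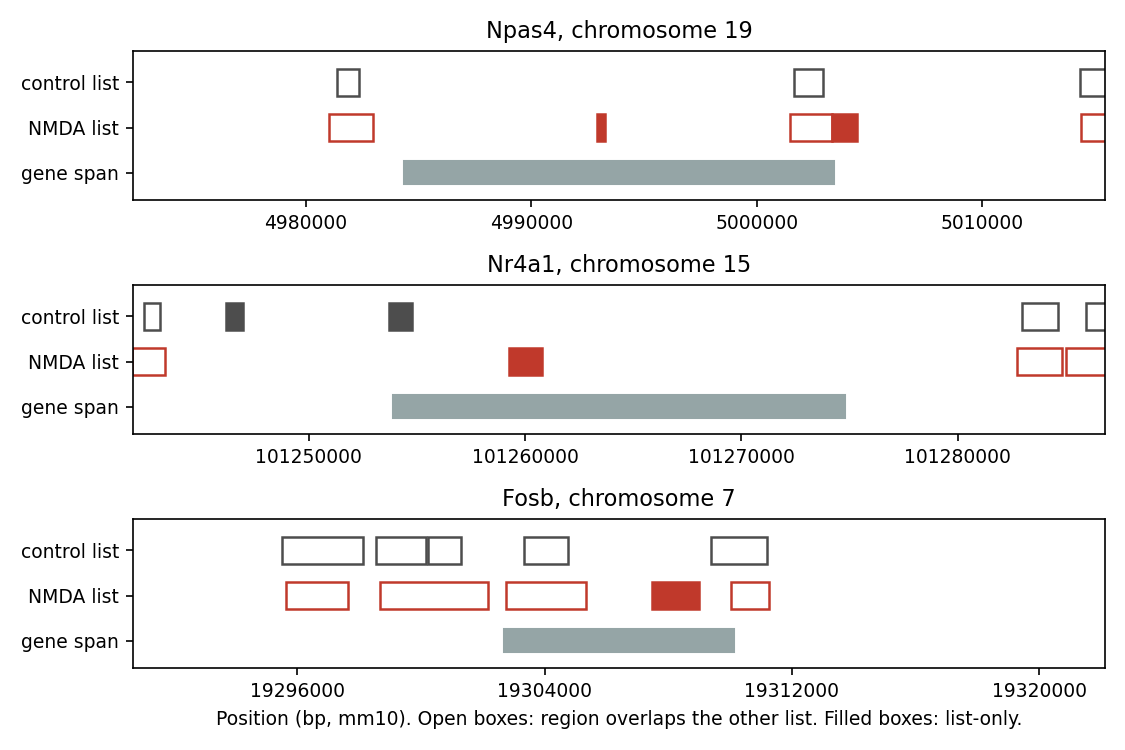
Regions of the control list (grey outlines) and the NMDA list (red outlines) around Npas4, Nr4a1 and Fosb, with the annotated gene span (grey bar) and position in bp on mm10 on the horizontal axis. Open boxes overlap a region of the other list, filled boxes do not, and boxes at the edge of a map run on beyond it. The NMDA-only region at Npas4 (5003360 to 5004434) lies beside a shared region, and Fosb, chosen after its values were seen, has an NMDA-only region inside the gene (19307469 to 19309003).

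Later activity-regulated genes include secreted factors and signalling regulators. Of the 20 members 12 had a shared region at an end, against 5.73 in random lists (adjusted permutation p = 0.0234), and 17 had one in the gene body against 10.99 (adjusted permutation p = 0.0156). In the body 2 had an NMDA-only region against 3.34 (adjusted permutation p = 1) and 4 a control-only region against 2.30 (adjusted permutation p = 0.670). Differences between this list and the immediate early genes were not tested. The strongest at ends were Crem (chromosome 18, 3336733 to 3338206, −log10 p 726), Rasgrp1 (chromosome 2, 117341031 to 117343489, 579.7), Vgf (chromosome 5, 137024054 to 137026230, 494) and Tiparp (chromosome 3, 65528469 to 65529783, 402). The call at gene ends was lost under 3 of 9 alternative settings, over which the adjusted permutation p ran from 0.0018 to 0.302. No member had an NMDA-only region at an end, and Rgs2 had a control-only region there (chromosome 1, 144003359 to 144005005, 60.2). The list of 17 genes for CTCF, cohesin and topoisomerases also holds Zfp143, Yy1 and Maz, which are transcription factor genes. Of the 17, 7 had a shared region at an end against 5.21 (adjusted permutation p = 0.513), the strongest at Pds5b (chromosome 5, 150673078 to 150674326). None had a list-only region there. In the body 4 members had an NMDA-only region against 3.96 (adjusted permutation p = 1), Nipbl, Top1, Wapl and Zfp143, with the strongest in Zfp143 (chromosome 7, 110069489 to 110070295, −log10 p 31.3). A control-only region lay in the body of Ctcf (chromosome 8, 105677639 to 105678573, 79.0) and of Top2a, 2 members against 2.69 (adjusted permutation p = 1). The 6 genes named for list-only regions in the body were chosen after their values were seen.

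Clustered protocadherins, cell adhesion genes whose choice of promoter involves CTCF, had the highest count of NMDA-only regions at gene ends among the 18 lists. Of the 57 members 14 had one, against 2.32 in random lists (adjusted permutation p = 0.0018, with the unadjusted p of 0.0001 the smallest that the random lists can give). These were 14 distinct regions. The call was kept under 7 of 7 alternative settings. Control-only regions lay at an end of 4 members against 2.52 (adjusted permutation p = 1). Spans in the cluster overlap and many members share an end, so that 1 region can count for several members. The 36 members with a shared region at an end rested on 20 distinct regions. The 34 members with an NMDA-only region in the body rested on 14 and the 18 with a control-only region on 4. Random lists do not share regions in this way, so no test is given for these 3 counts. The strongest NMDA-only regions at ends lay at Pcdhb17 (chromosome 18, 37484417 to 37485184, −log10 p 50.7), Pcdhb14 (37447132 to 37448045, 47.8), Pcdhb11 (37421170 to 37422039, 37.1) and Pcdhga3 (37674037 to 37674691, 36.7). In the first replicate column Pcdhb17 had 10.0 and Pcdhb14 had 10.9, against 40.7 and 36.9 in the second. The genes of the cluster are neighbours of related sequence, so they are not independent, and the placement of reads among them could not be checked. Counted as regions, the cluster (chromosome 18, 36930285 to 37841873) held 38 NMDA regions, of which 14, or 36.8% (23.4 to 52.7), were NMDA-only. Regions elsewhere with the same signal deciles had 29.4%, and the difference of 7.45 points (−5.68 to 20.2) had an interval that included 0. Of the 28 control regions in the cluster, 4 were control-only.

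Ribosomal protein genes had shared regions at the ends of 37 of 83 members, against 18.3 in random lists (adjusted permutation p = 0.0009), the strongest at Rps3a1 (chromosome 3, 86141960 to 86143377) and Rpl10a (chromosome 17, 28327723 to 28329652). NMDA-only regions lay at the ends of 8 members against 2.95 (adjusted permutation p = 0.0684), the strongest at Rpl37 (chromosome 15, 5119174 to 5120424, −log10 p 36.8). This was past the threshold at the stricter score and with all gene types. In the bodies 10 members had an NMDA-only region against 3.74 (adjusted permutation p = 0.0315), and 40 a shared region against 22.3 (adjusted permutation p = 0.0009). Both calls in the bodies were lost with random lists not matched on gene length.

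Of the 30 synaptic genes 27 had a shared region in the body against 21.1 (adjusted permutation p = 0.0247). An NMDA-only region lay in the body of 11 synaptic genes against 7.56 (adjusted permutation p = 0.604, and 0.0132 without length matching), the strongest in Dlg2 (chromosome 7, 92104562 to 92106126, −log10 p 89.1) and Nrxn3 (chromosome 12, 89554438 to 89555664, 86.0). These 2 regions had 16.2 and 14.3 in the first replicate column, against 73.0 and 71.7 in the second. The 18 ionotropic glutamate receptor genes had 8 members with an NMDA-only region in the body against 5.95 (adjusted permutation p = 0.633, and 0.0132 without length matching), the strongest in Grin2a (chromosome 16, 9865575 to 9866300, 44.6). Voltage-gated calcium channels had a control-only region in the body of 8 of 15 members against 3.598 (adjusted permutation p = 0.103). This changed to an adjusted permutation p of 0.0009 without length matching and to 2 members against 1.958 at the stricter score. All 15 had a shared region in the body against 12.2 (adjusted permutation p = 0.100), which was past the threshold at the stricter score and without length matching. Replication-dependent histone genes had a shared region at the end of 10 of 66 members against 4.59 (adjusted permutation p = 0.0508) and in the body of 11 against 5.37 (adjusted permutation p = 0.0349). The 10 members rested on 9 distinct regions. They were 15.2% of the list, below the 25.8% of all protein-coding genes with a shared region at an end. The count at the ends was thus high only against genes of similar length. The call at the ends was gained under 6 of 9 alternative settings, and the count in the body lay below the mean of random lists not matched on gene length.

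None of the remaining lists had more members with a region at an end than random lists in any class, at the threshold of 0.05. Shared regions lay at the ends of 8 of 39 Hox genes (random mean 9.55), 6 of 23 imprinted genes (6.52) and 8 of 17 neuron identity genes (5.35). Among markers of other cell types they lay at 5 of 10 astrocyte (2.79), 4 of 10 oligodendrocyte (2.74), 1 of 10 microglia (2.4997) and 1 of 8 endothelial genes (2.30). Liver-restricted genes, a negative list, had 2 of 15 (3.87). The 1106 olfactory receptor genes, the other negative list, had fewer than random lists in each class at ends, with NMDA-only regions at 3 members against 14.8, control-only regions at 0 against 11.4 and shared regions at 7 against 88.2 (adjusted permutation p = 0.0018 for each).

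**Figure D4:**
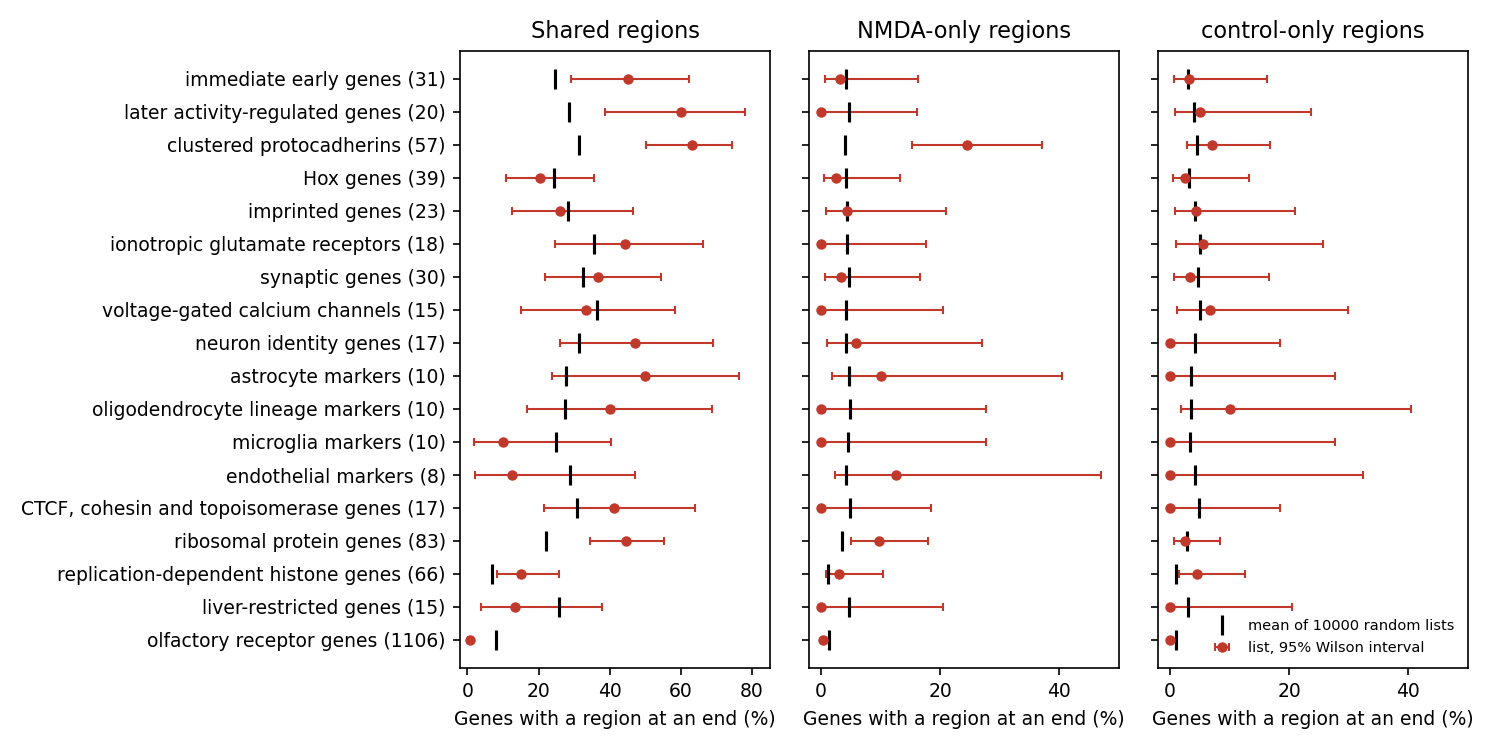
Percent of the members of each fixed gene list (horizontal axis, number of members in brackets) with a shared, NMDA-only or control-only region within 1 kb of a gene end. Red points are the lists with 95% Wilson intervals and black bars the means of 10000 random lists matched on gene length. A region at an end that several members share counts for each of them, as in the protocadherins. Clustered protocadherins stand at 24.6% for NMDA-only regions, and immediate early genes at 45.2% for shared regions.

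Inside genes, NMDA-only regions were most numerous in Camta1, which encodes a calmodulin-binding transcription activator (chromosome 4, 151059523 to 151861768), with 9 NMDA-only, 2 control-only and 24 shared regions. Atxn1 (chromosome 13, 45549755 to 45964991) and Cdh13 (chromosome 8, 118140017 to 119324929) had 6 each, beside 0 and 4 control-only regions. Eif4g3, Igsf21, Septin9, Fry and Nav2 had 5 each. Csmd2 (chromosome 4, 127986505 to 128567660) had the most control-only regions, 5, with no NMDA-only region, and Cdh13, Ebf2, Rbms3 and Rtn1 had 4 each. NMDA-only summits lay a median of 15413.5 bp from the nearest shared summit, against 45417 bp for shuffled positions (range of 100 shuffles 42716 to 48674.5). Control-only summits lay at 17222 bp against 45528.5 bp (41429 to 49482). Shuffled positions were drawn evenly along each chromosome. The distances therefore do not show that list-only regions lie nearer to shared regions than other regions do.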

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

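The tests of signal, of library spread and of the X chromosome in this part were chosen after the results were seen. The test of region edges was written before its result was seen.

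Regions outside the assembled chromosomes entered no comparison. There were 5 in the control list and 7 in the NMDA list, a signal in data that the comparisons do not use and above the limit that a count of 0 allows. A region on an unplaced contig had the highest −log10 p of the NMDA list (4002) and the second highest of the control list (5231).

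With sharing defined by a 1 bp overlap, NMDA-only regions lay at gene ends less often than shared regions. Under that definition weaker signal is argued against as the whole cause, since the difference against shared regions of the same signal bins was −10.6 points (−12.2 to −9.02). The difference was smaller, but still below 0, with bins from the first replicate column alone. The argument does not extend to summits within 100 bp, where the matched interval included 0. Near misses, regions of the 2 lists that lie just apart, were joined by extending regions by 500 bp. The difference was then −10.9 points (−12.5 to −9.38), which argues against near misses as its cause. Extension can only add shared regions, so it cannot tell whether the 1 bp rule joins too many. Summits within 100 bp, a stricter rule, gave 0.663 points (−0.791 to 2.13). Offset edges or summits within overlapping regions thus stay open as a cause. Spread between ChIP libraries stays open and cannot be told apart from an effect of stimulation. A comparison of the strongest control regions with those of each NMDA replicate could not decide it: at 0 of 5 list depths did the strongest NMDA regions hold at least 50% of the NMDA-only regions, and the highest share held was 36.0%. An effect of NMDA on binding at gene ends may contribute and is untested, because no control replicate has its own values here.

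NMDA-only regions were more frequent on the X chromosome, at 21.2% of 831 regions against 15.4% of autosomal regions. Weaker signal of X-linked regions is argued against as the whole cause, since the difference at matched signal was 3.89 points (1.38 to 6.39). The matched difference in the control list was 0.0762 points (−1.97 to 2.31), an interval too wide to exclude a property of X-linked regions that acts in either list. The sexes of the embryos behind each culture could differ and were not tested.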

How the results depend on the processing

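Alternatives with 20 signal bins, single replicate columns for gene-end shares and other settings for the strongest regions, and shared regions placed by the control list or by either list, were chosen after seeing the data. Of 698 values under alternatives, 633 kept their call or range, 526 of them among 558 single-list values, where staying uncalled counted as kept. Other values kept theirs less often. The overlap definition moved the shares most. The shared percent of the control list was 88.9 with the NMDA list limited to equal length, 85.2 with a reciprocal overlap of 50%, 91.6 with regions extended by 500 bp, 94.4 at the stricter score and 84.1 with summits within 100 bp. The shared percent of the NMDA list was 88.3, 79.6, 85.7, 82.0 and 78.6 in the same order. Control-only regions numbered 5005 with reciprocal overlap, 1467 at the stricter score and 5367 with summits within 100 bp. The percent of NMDA-only regions below the median signal ran from 97.2 to 99.0 with a single replicate column. Ranked by score, where many regions share the ceiling, it was 80.1, and 93.3 for control-only regions. NMDA-only summits lay a median of 19700 bp from a shared summit at the stricter score.

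The gene-end difference between NMDA-only and shared regions turned to 0.278 points with reciprocal overlap and 4.29 points with summits within 100 bp, where the matched difference was 0.663 points. Summits within 100 bp made 14.1% of shared regions at gene ends NMDA-only, against 6.36% inside and 4.35% between genes, and reciprocal overlap 8.41% against 5.187% and 5.194%. The source of this was not tested. The matched control-only difference lost its call at 1.60 points with all gene types and 1.09 points with extended regions. NMDA-only regions stayed below control-only regions under all 7 alternatives, from −17.3 to −5.33 points. Among the strongest regions NMDA minus control was −13 points at 300, −7.07 at 3000 and −1.32 at 30000 regions, but past 3000 this rested on the second replicate. By the first column alone the NMDA share was 21.01% against 21.29% at 10000 and 17.08% against 17.39% at 30000, with overlapping intervals.

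With pieces of split control regions counted, immediate early genes with an NMDA-only region at an end numbered 8 with reciprocal overlap and 8 with summits within 100 bp. Both were past the threshold, against random lists matched on gene length only. Immediate early genes with a shared region numbered 9 within 500 bp, 13 with the NMDA list limited and 9 with reciprocal overlap. At the stricter score and with summits within 100 bp they numbered 11 each, and no call was left under any of these settings. Placed by the control list they numbered 15 and by either list 17, both past the threshold. Later activity-regulated genes with a shared region numbered 7 within 500 bp, 10 with reciprocal overlap and 10 with summits within 100 bp, with no call left. Lists with more NMDA-only members at ends than random lists numbered 2 with all gene types, with reciprocal overlap, at the stricter score and with summits within 100 bp. Lists with more shared members numbered 2 within 500 bp and 2 with reciprocal overlap. In gene bodies, random lists not matched on length gave 2 lists with fewer NMDA-only, 2 with fewer shared and 2 with more control-only members, and the stricter score gave 0 with more control-only members. The clustered protocadherins, whose members share regions, count among these lists. Without length matching, the 11 histone genes with a shared region fell below the random mean of 31.9, as gene lengths then differed.

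No paired analysis was possible because each list was built over both replicates. For the same reason leaving out a replicate was possible only for the signals of the NMDA list. Motif alternatives and random lists matched on CpG content were not run, since they need a genome sequence. Depth is unknown, so regions missing from 1 list may lie just below its threshold: at least 98.5% of each list-only class lay below the median signal of its list.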

Other observations

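The tests of region width in this part were chosen after the result was seen. At Nr4a3 a control region of 4338 bp (chromosome 4, 48044425 to 48048762) overlapped 3 NMDA regions of 584 to 1426 bp. Of 18 shared NMDA regions at immediate early gene ends, 14 were narrower than their control partner, but these include pieces of split regions that share a partner. Of the 14 control partners, 5 overlapped several NMDA regions, against 178 of 5332 over all gene ends. Shared control regions with summits at immediate early gene ends had a median width of 2313 bp, against 1351 bp at all gene ends. The source of the more frequent splitting was not tested. The 14 control partners were also counted once each, against the summed width of the NMDA regions that overlap them. Of these, 7 had narrower and 7 had wider NMDA regions, with a median ratio of 0.962. The narrower single regions were thus in part a product of splitting. Narrower regions throughout the NMDA list are argued against as their cause, since the ratio for single regions over all shared gene ends was 0.988. The matched test asked only whether these control regions lost covered width. NMDA regions covered a median of 87.5% of the bases of the 15 control regions at these ends, within the 78.0 to 97.3% of random sets of gene-end control regions matched on width and signal. A small loss could stay within that range, and covered width need not change when a region splits or its summit moves. By the summit definition, summits lay apart in 38.9% (20.3 to 61.4) of the 18 NMDA regions, pieces of split regions included, against 14.1% over all gene ends. That contrast was not put to a matched test. Whether stimulation altered regions at these genes in particular was thus not decided.

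The strongest NMDA-only region, singled out after its values were seen, lay on chromosome 2 (98666946 to 98667304, 359 bp). Its −log10 p was 1403 in the first replicate column and 87.9 in the second, a ratio of 15.96, against a median ratio of 0.685 over the list. Regions prone to artefactual signal were not filtered out here, and whether this region is one was not tested.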
